A study of Homo sapiens with 5 samples.

How the data were processed

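RNA sequencing was used to measure gene expression in HCT116, a human colorectal cancer cell line. Cells received a control siRNA (2 libraries, control 1 and control 2), an siRNA against SP1 (1 library), an siRNA against SP3 (1 library) or both siRNAs (1 library), per the labels. An siRNA is a short double-stranded RNA that lowers the transcript it is matched to. The labels state total RNA, extraction with Trizol and Illumina libraries. Whether the libraries were selected for polyadenylated RNA, whether they kept the strand, the siRNA sequences and their amounts, and the hours of treatment are not given in the sources used here.

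The authors deposited 1 table per library with a gene symbol and an FPKM value, the fragments per kilobase of transcript scaled to the counted fragments of the library. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.0.5, Cufflinks 2.2.1 and HTSeq 0.9.1 were used, with no role or order stated. The genome build, the annotation and any filter on reads are not given in the sources used here, so no coordinates are printed. Each table listed 20030 symbols in the same order. Of these, 18724 were found in human gene name tables. Another 27 symbols read as calendar dates, the form that spreadsheets give to some gene names, and were not named. No mitochondrially encoded gene of the list set aside for RNA quality was present. Where strand was not kept, reads of overlapping or antisense genes cannot be told apart, and near-identical genes can share reads.

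FPKM values are not read counts, but the deposited values keep the counting steps. Relative depth was taken from the steps of low values, and absolute depth from 208 genes with a single annotated transcript in GENCODE 29. The smallest whole transcript length that gave whole reads in all 5 libraries was then sought for each gene, with a tolerance of 0.02 reads. Whole reads were found for 17125 of 17125 genes above 0 (100%), against 0.2% of 500 genes whose values had first been jittered at random with an SD of 1%. The smallest length can be the true length over a common factor, so a recovered read number is a lower limit. The library denominators were 15681880 and 15899164 reads for control 1 and control 2, 15354043 for the SP1 siRNA, 15970519 for the SP3 siRNA and 14678068 for both. The recovered reads summed to 99.19 to 99.29% of these. Recovered reads served for depth, for 95% Poisson intervals, for a floor of 3 reads where a gene had 0, and for 1 added alternative test. These intervals and floors cover counting error alone.

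Because the unit was FPKM, the test was limma 3.58.1 (R 4.3.3, empirical Bayes with a trend on mean level) on log2(FPKM + 1), and the count-model tests foreseen in case of counts were not run. Differences are on that scale, which understates the change of genes with low values. Genes with at least 1 FPKM in at least 1 library were tested, 11728 in all. The model had 1 mean per group over all 5 libraries. Its 1 residual degree of freedom came from the 2 controls, with 13.98 prior degrees of freedom shared across genes. The 3 knockdown libraries were thus assumed to vary like the controls, and no difference has a replicate check on the knockdown side. Nothing in the labels says that the controls were separate cultures, so p-values measure only the spread between these samples, which may be technical. The 6 comparisons were each knockdown against the controls, the double knockdown against each single knockdown, and the interaction, which is the double knockdown difference minus the sum of the single ones. A Benjamini-Hochberg adjusted p under 0.05 was the threshold. A count that needs no test was made beside it: genes with a mean of at least 5 FPKM that differed by at least 2-fold in the same direction from each control.

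A total of 27 gene lists was fixed before the data were examined. For each list with at least 3 measured members the median difference in each comparison with the controls was given with its percentile among 10000 random lists of the same size matched on mean level, and the same median between the 2 controls. The percentile describes these libraries and is not a p-value. Named genes were SP1 and SP3, the 8 largest rises and 8 largest falls past the threshold in each comparison with the controls (mean of at least 5 FPKM, same direction against each control), up to 4 members per list by smallest p, and the 3 largest each way in the other comparisons. Unnamed loci and pseudogenes were skipped, and some list members that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

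The test was run on simulated data first, with 50 genes changed at each of 4 fold sizes, drawn at the depth of these libraries. Spread beyond counting error (dispersion) was set to 0.002491 for all genes, a trimmed mean from the 2 controls. A median-based estimate was 0.000149. Spread that differs between genes, or that is particular to the knockdown libraries, was thus not simulated. For the SP1 siRNA (11144 genes), 84% of genes changed 1.5-fold were recovered, for the SP3 siRNA (11178 genes) 90%, and for both (11171 genes) 90%. At 2-fold and above, 98 to 100% were recovered in each. There were 68, 56 and 71 false calls, beside at most 200 true ones in each comparison. In these simulated data, false calls were thus a larger share of all calls than the adjusted p threshold is meant to allow. Adjusted p-values may therefore understate the share of false calls. Unchanged groups against the same controls were simulated 20 times, with that same dispersion, to give the similarity that shared controls produce alone.

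For the closing section, 7-base words were scanned in the longest annotated 3' UTR of 10801 genes (GENCODE 29), 15768 words each present in at least 100 genes, with UTR length, base composition and mean level as covariates (Python 3.11.15, numpy 2.4.6). Genes with no annotated 3' UTR were not searched. A shift of -0.3 planted on 1 word in shuffled data ranked 1 with a z of -13.78. The alternatives tried were no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, a limit of 1 on the log2 scale, the libraries of 1 comparison alone, an additive model, each control left out, and a 1.5-fold limit or a mean of at least 1 FPKM for the counts by size. Median-ratio scaling, limma-voom on recovered reads, removal of GC or length trends, crossed controls for the ratio of the double knockdown to the sum, the lowest interaction that a level of 0 allows, and the direct difference between the SP3 and SP1 siRNA libraries were added after the data were seen.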

Results

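Transcript levels were measured by RNA sequencing in HCT116 colorectal cancer cells after siRNA knockdown of SP1, of SP3 or of both. SP1 and SP3 are zinc finger transcription factors of one family that bind GC-rich promoter sites. There were 2 control libraries and 1 library each for the SP1 siRNA, the SP3 siRNA and the double knockdown. The libraries had 14678068 to 15970519 counted reads, and 10654 to 11232 genes reached 1 FPKM. The 2 controls differed by a median log2 of -0.03 with an SD of 0.133 across 11728 genes, and 90% of genes lay between the percentiles at -0.25 and 0.17. Among 12904 genes with at least 20 reads, 19% differed between the controls by more than counting error allows in 5%, so they were counted as 2 libraries. Across genes, which are not independent replicates, log2 levels correlated at 0.9972 between the controls, 0.9822 between the SP3 siRNA and double knockdown libraries, 0.9696 between the SP1 siRNA and double knockdown libraries, and 0.9444 between the single knockdowns. By gene list, the control difference stood out among matched random lists at percentile 0.04 or lower for mitosis (median -0.22) and interferon genes (-0.14), and at percentile 99.99 or higher for histone (0.31), immediate early (0.09), autophagy (0.08) and ATF4 genes (0.08).

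The targeted transcripts were lower in the libraries labelled for them. SP1 stood at 36.9 ± 0.400 FPKM in the controls (SD, n = 2) and at 15.8 FPKM with the SP1 siRNA, 42.9% of the control level (95% Poisson interval 39.4 to 46.5%). SP3 stood at 13.1 ± 0.188 FPKM in the controls and at 5.42 FPKM with the SP3 siRNA, 41.3% of control (38 to 44.8%). In the double knockdown SP1 was at 43.6% (40 to 47.4%) and SP3 at 50.7% (46.9 to 54.8%). The SP3 siRNA library also held less SP1, 74.5% of control (70 to 79.2%, log2 difference -0.41 ± 0.07 SE, limma adjusted p = 0.000165), but in the additive model the difference was -0.23 and missed the threshold (adjusted p = 0.284). With the SP1 siRNA, SP3 was at 109% of control (104 to 115%), a log2 difference of 0.12 ± 0.09 that did not pass the limma threshold (adjusted p = 0.259).

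**Figure D1:**
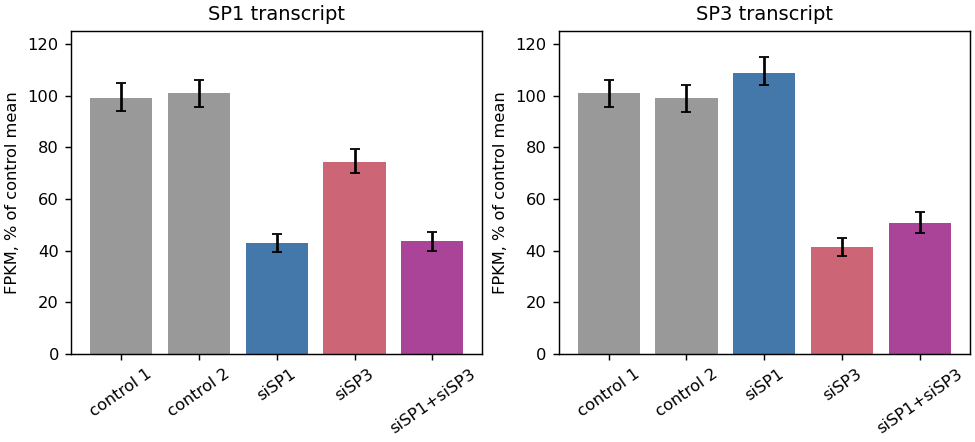
Bars show the FPKM of the SP1 transcript (left) and the SP3 transcript (right) in each of the 5 libraries as a percentage of the mean of the 2 controls, with 95% Poisson intervals of the recovered reads as error bars. SP1 was at 42.9% of control with the SP1 siRNA and at 43.6% in the double knockdown, and SP3 at 41.3% with the SP3 siRNA and at 50.7% in the double knockdown.

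The first comparison asked which transcripts change when SP1 is lowered. With the SP1 siRNA, cyclin D1 (CCND1), which drives entry into S phase, fell from 359 ± 1.06 FPKM in the controls to 65.8 FPKM (log2 difference -2.43 ± 0.06, limma adjusted p = 1.17e-13). The neuronal-type glucose transporter SLC2A3 fell from 70.5 and 63.9 FPKM to 5.03 FPKM (-3.50 ± 0.08, adjusted p = 1.17e-13), the chemokine CCL20 from 12.8 and 12 FPKM to 0.387 FPKM (-3.27 ± 0.11), and the large scaffold protein gene AHNAK from 124 and 119 FPKM to 16.8 FPKM (-2.78 ± 0.06). Falls of -2.61 ± 0.13 to -2.33 ± 0.10 followed for S100A9, a calcium-binding protein of inflammation, NDUFB2, a subunit of respiratory complex I, ALDH1B1, a mitochondrial aldehyde dehydrogenase, and THBS1, the matrix protein thrombospondin 1. The steepest rise was that of ARL14EPL, from 8.06 and 7.84 FPKM to 97.3 FPKM (3.46 ± 0.08, adjusted p = 1.17e-13). TOMM22, a receptor for protein import into mitochondria, rose from 8.88 and 8.67 to 57.8 FPKM (2.59 ± 0.07), the endoplasmic reticulum peroxidase PRDX4 from 21.6 and 19.6 to 114 FPKM (2.42 ± 0.07), and the transcription factor KLF2 from 6.27 and 6.68 to 33.5 FPKM (2.21 ± 0.08). ABRAXAS1, a scaffold of the BRCA1-A complex, rose by 2.33 ± 0.10, METTL27 by 2.23 ± 0.15, AMN1 by 2.22 ± 0.09 and ADPRHL1 by 2.09 ± 0.11. In the additive model, where the double knockdown's departure from the sum counts as spread, ADPRHL1, AHNAK, ALDH1B1, CCND1, METTL27, NDUFB2 and SLC2A3 passed the threshold. The others did not, at 1.58 for ABRAXAS1, 1.39 for AMN1, 2.27 for ARL14EPL, -2.1 for CCL20, 1.06 for KLF2, 1.47 for PRDX4, -1.55 for S100A9, -1.61 for THBS1 and 1.47 for TOMM22 (adjusted p 0.0603 to 0.242).

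Genes of cell division fell together with the SP1 siRNA. The list counts here and below stand beside 65.4% of all tested genes called in this comparison, 4283 higher and 3383 lower. Of 36 measured mitosis genes 35 fell and none rose, with a median of -1.11. Among them the log2 differences were -2.04 ± 0.13 for KIF20A, a kinesin of cytokinesis, -1.45 ± 0.08 for MAD2L1, a spindle checkpoint protein, -1.35 ± 0.09 for AURKB and -1.29 ± 0.07 for CDC20. This list also separated the controls, by a median of -0.22 for control 2 minus control 1. Of 38 DNA replication genes 28 fell and 2 rose (median -0.46), among them FEN1, the flap endonuclease, from 23.0 and 23.1 to 3.91 FPKM (-2.29 ± 0.09) and RRM2, a ribonucleotide reductase subunit, from 66.1 and 64.5 to 18.0 FPKM (-1.80 ± 0.07). Of 26 cyclins and CDK inhibitors 16 fell and 4 rose (median -0.50), including CCNA2 (-1.28 ± 0.09) and the inhibitor CDKN2D (-1.30 ± 0.08). Of 38 DNA repair genes 15 fell and 11 rose (median -0.19), with FANCG at -1.15 ± 0.10 and RAD54L at -1.0 ± 0.10. Of 31 textbook targets of SP1, 18 fell and 8 rose (median -0.45), and the named ones were CCND1, TK1 (-1.26 ± 0.06), TYMS (-1.14 ± 0.07) and CDKN1A (-0.74 ± 0.06). Each of these named targets is also on the replication or the cyclin list, so the textbook list is not separate evidence from those lists. The medians of mitosis, replication, cyclins and textbook targets lay at percentile 0 of 10000 matched random lists, and that of repair at 0.67. Of these named genes CCND1, CDC20 and CDKN1A passed the threshold in the additive model. The falls of the others shrank there and missed it, to -0.48 for AURKB, -0.51 for CCNA2, -0.88 for CDKN2D, -0.56 for FANCG, -1.44 for FEN1, -0.96 for KIF20A, -0.53 for MAD2L1, -0.33 for RAD54L, -0.53 for RRM2, -0.42 for TK1 and -0.6 for TYMS (adjusted p 0.072 to 0.576).

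Metabolic and signalling lists moved less evenly. Of 25 cholesterol synthesis genes 21 fell and 1 rose (median -0.54), with EBP (-1.52 ± 0.07) and DHCR7 (-1.10 ± 0.06), enzymes of the late pathway. Of 39 oxidative phosphorylation genes 22 fell and 8 rose (median -0.19), among the falls CYC1 (-1.33 ± 0.06) and NDUFS3 (-1.36 ± 0.06). Of 32 glycolysis and hypoxia genes 18 fell and 10 rose (median -0.31). ANKRD37 fell by 1.28 ± 0.06 and PFKL, a phosphofructokinase, rose by 1.09 ± 0.07. Of 27 mesenchymal and matrix genes 14 fell and 8 rose (median -0.26), including ITGA2 (-1.30 ± 0.07) and PLAU (-1.22 ± 0.07). Of 21 NF-kB and cytokine genes 10 fell and 5 rose (median -0.23), with ICAM1 at -1.20 ± 0.09 and BIRC3 at -1.13 ± 0.07. Leukocyte markers fell in this library too, 4 of 6 with 1 rise (median -0.92). What share of the lower NF-kB genes comes from other cells was not tested. Interferon genes numbered 22, of which 12 fell and none rose (median -0.33), with ISG15 at -1.24 ± 0.06. The control pair differed by -0.14 on that list. Of 20 epithelial genes 9 fell and 3 rose (median -0.17), with CLDN4 at -1.50 ± 0.05. Of 16 fatty acid synthesis genes 7 fell and 5 rose (median -0.13), with ACSS2 at -1.59 ± 0.07. FASN (-0.45 ± 0.06) and SCD (-0.43 ± 0.05) fell in this fit, but in the additive model they lay at 0.106 and 0.06 with adjusted p of 0.809 and 0.881. BIRC3, ISG15 and ITGA2 passed the threshold in that model, while it was missed by ACSS2 (-0.87), ANKRD37 (-0.73), CLDN4 (-0.99), CYC1 (-0.88), DHCR7 (-0.39), EBP (-0.92), ICAM1 (-0.68), NDUFS3 (-0.95), PFKL (0.68) and PLAU (-0.81), with adjusted p of 0.0619 to 0.476. The medians lay at percentile 0 of the random lists for cholesterol, 0.13 for glycolysis, 0.14 for interferon, 0.565 for mesenchymal, 1.18 for oxidative phosphorylation, 1.85 for NF-kB, 4.38 for epithelial and 10.9 for fatty acid genes.

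Other lists went both ways. WNT targets had 8 rises and 5 falls of 16 (median 0.26), with EPHB2 at 1.28 ± 0.11 and MYC at 0.61 ± 0.06 among the rises. The SP and KLF family had 9 rises and 5 falls of 18 (median 0.20), with KLF7 at 1.1 ± 0.10. This list holds SP1 and SP3 themselves, and its falls here include SP1, the siRNA target. Targets of p53, which is intact in this line, had 11 rises and 8 falls of 26 (median 0.005). CCNG1 rose by 1.09 ± 0.06 and BAX by 0.75 ± 0.06. Apoptosis regulators had 10 rises and 10 falls of 29, with a median of 0.08 and a mean of -0.07, and MCL1 lay at -0.71 ± 0.06. Autophagy and lysosome genes had 12 rises and 10 falls of 32 (median 0.07). ATG12 rose by 1.40 ± 0.06 and LAMP1 fell by 1.08 ± 0.07. Genes of the NRF2 and antioxidant list had 5 rises and 9 falls of 21 (median -0.14), with SRXN1 at -1.11 ± 0.07. The ATF4 and unfolded protein list had 11 rises and 11 falls of 30 (median -0.002), with SLC7A5 at -1.45 ± 0.07 and MTHFD2 at 0.78 ± 0.06. Immediate early genes had 7 rises and 8 falls of 23 (median -0.01), with FOSL1 at 1.06 ± 0.06. Cytosolic ribosomal protein genes had 21 rises and 6 falls of 54 (median 0.08), with RPL11 at 0.66 ± 0.05 and RPS16 at -0.79 ± 0.05. Histone genes had 2 rises and 6 falls of 10 (median -0.71), and on these the controls differed by 0.31. This list was set as a marker of RNA type, since most canonical histone transcripts lack a poly(A) tail, and how RNA was selected is not given in the sources used here. Adjusted over the list alone, the counts of rises and falls were 5 and 11 for NF-kB, 6 and 8 for fatty acid synthesis, 11 and 18 for glycolysis, 11 and 12 for ATF4, 10 and 11 for apoptosis, 12 and 15 for repair, 6 and 9 for the antioxidant list and 5 and 16 for cyclins, and were as over all genes for the other lists. With the additive model MCL1, MTHFD2 and SLC7A5 passed the threshold, and ATG12 (0.8), BAX (0.54), CCNG1 (0.72), EPHB2 (0.86), FOSL1 (0.43), KLF7 (0.61), LAMP1 (-0.75), MYC (0.4), RPL11 (0.34), RPS16 (-0.54) and SRXN1 (-0.8) did not (adjusted p 0.0616 to 0.377). Percentiles were 89.9 for WNT, 81.9 for SP and KLF, 40.7 for p53, 64.1 for apoptosis, 65.2 for autophagy, 6.95 for antioxidant, 38.3 for ATF4, 31.9 for immediate early, 65.7 for ribosomal protein and 0 for histone genes.

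In all, limma called 7666 of 11728 genes with the SP1 siRNA, 4283 higher and 3383 lower, of which 521 rose and 493 fell by at least 2-fold. Without a test, 264 genes were higher and 352 lower by at least 2-fold than each control among 7127 genes, against 0 between the 2 controls. The call count rests on the spread of 2 controls alone. With median-ratio scaling the split was nearly even, at 3725 higher and 3649 lower. In the additive model, where the double knockdown served as a further library, limma called 900 genes for the SP1 siRNA, 432 higher and 468 lower, and of 100 named genes 31 kept their side of the threshold, 67 lost it and 2 reversed. A mean of at least 5 FPKM left 5109 and no filter 4180.

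**Figure D2:**
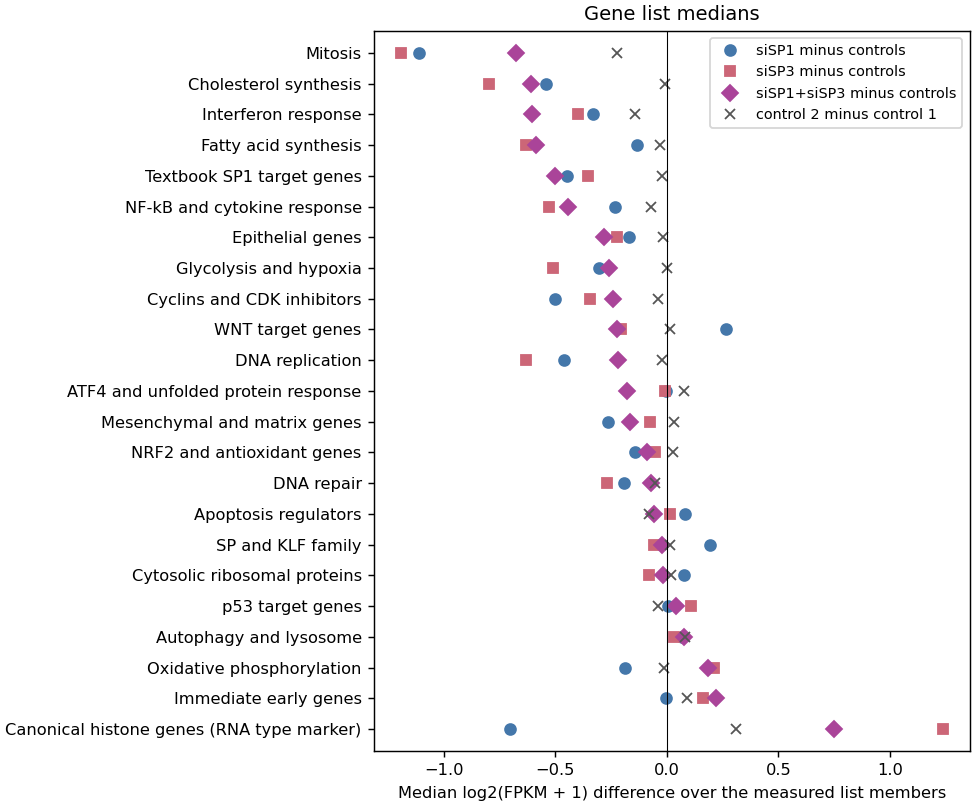
Points show the median log2(FPKM + 1) difference over the measured members of the 23 gene lists with at least 10 of them, for each knockdown library minus the mean of the 2 controls, with crosses for control 2 minus control 1. Mitosis stands at -1.11, -1.19 and -0.68 for the SP1 siRNA, the SP3 siRNA and both, against -0.22 between the controls, and histone genes stand at -0.71, 1.24 and 0.75 against 0.31.

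The second comparison asked the same for SP3. With the SP3 siRNA, the secretory granule proteins SCG2 and VGF were among the steepest rises. SCG2 rose from 2.88 and 3.47 FPKM to 30.4 FPKM (2.92 ± 0.10, limma adjusted p = 8.7e-12) and VGF from 35.9 and 34.3 to 241 FPKM (2.75 ± 0.06, adjusted p = 4.34e-13). Cyclin E1 (CCNE1), the partner of CDK2 at the start of S phase, rose from 15.5 and 17.1 to 78.2 FPKM (2.2 ± 0.08), RGS2, a regulator of G protein signalling, from 47.7 and 49.2 to 238 FPKM (2.27 ± 0.06), ANKRD52 by 2.43 ± 0.08 and TMEM158 by 2.26 ± 0.08. TOMM22 (2.38 ± 0.07) and KLF2 (2.21 ± 0.08) rose here as well. Among the falls, the acute phase protein gene SAA1 went from 21 and 20.6 FPKM to 0.877 FPKM (-3.54 ± 0.11, adjusted p = 3.03e-12). S100A9 went from 11.5 and 14 FPKM to 0.109 FPKM, 1 read, which is 117-fold lower with a counting interval of 21- to 4630-fold. It fell together with the leukocyte markers LYZ, TYROBP and CD14, and whether this is regulation or a loss of other cells present in the control cultures was not settled. Further falls were those of PFKFB4, which makes an activator of glycolysis (-2.49 ± 0.07), KIF20A (-2.40 ± 0.13), SRPX (-2.40 ± 0.10), the collagen lysyl hydroxylase PLOD2 (-2.37 ± 0.07), the keratin KRT7 (-2.36 ± 0.08) and KCTD11 (-2.32 ± 0.09). The additive model kept ANKRD52, CCNE1, KRT7, PLOD2, RGS2, S100A9, SAA1, SCG2, SRPX and VGF past the threshold, but not KCTD11 (-1.19), KIF20A (-1.31), KLF2 (1.07), PFKFB4 (-1.68), TMEM158 (1.47), TOMM22 (1.25) or the markers LYZ (-2.11), TYROBP (-0.84) and CD14 (-0.6), whose adjusted p was 0.0543 to 0.238.

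Cell division genes were lower with the SP3 siRNA too. Its list counts stand beside 61.6% of all tested genes called, 3466 higher and 3759 lower. Of 36 mitosis genes 34 fell and 1 rose (median -1.19). TOP2A fell by 2.19 ± 0.10, ANLN by 1.64 ± 0.08 and AURKB by 1.52 ± 0.09, while the 1 that rose was CDC20, by 0.34 ± 0.07 to 91.8 FPKM. Of 38 DNA replication genes 32 fell and 1 rose (median -0.63), with the helicase subunit MCM2 at -1.96 ± 0.08, RRM2 at -1.86 ± 0.07, FEN1 at -1.52 ± 0.09 and TK1 at -1.38 ± 0.06. Of 26 cyclins and CDK inhibitors 18 fell and 6 rose (median -0.35). CCNA2 fell by 1.30 ± 0.09, and the inhibitor CDKN1C rose by 1.55 ± 0.07 alongside CCNE1. Of 38 DNA repair genes 19 fell and 4 rose (median -0.27), with XRCC3 at -1.39 ± 0.11 and BARD1 at -1.19 ± 0.12. BARD1, CCNE1 and CDKN1C passed the threshold in the additive model. Differences that missed it there were those of ANLN (-0.95), AURKB (-0.64), CCNA2 (-0.54), FEN1 (-0.66), MCM2 (-1.22), RRM2 (-0.59), TK1 (-0.54), TOP2A (-1.15) and XRCC3 (-0.75), with adjusted p of 0.0834 to 0.538. Mitosis and replication medians lay at percentile 0, cyclins at 0.12 and repair at 1.87.

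Lipid and glucose metabolism genes fell with the SP3 siRNA. Of 25 cholesterol synthesis genes 23 fell and 1 rose (median -0.80), including ACAT2 (-1.45 ± 0.07) and DHCR7 (-1.38 ± 0.06). Of 16 fatty acid synthesis genes 13 fell and 2 rose (median -0.63). FASN, the fatty acid synthase, fell from 520 and 500 to 156 FPKM (-1.70 ± 0.06), SCD, the stearoyl-CoA desaturase, from 932 and 911 to 357 FPKM (-1.36 ± 0.05), and ACLY by 1.15 ± 0.06. Of 32 glycolysis and hypoxia genes 22 fell and 6 rose (median -0.51), with GAPDH at -1.24 ± 0.05, PGAM1 at -1.35 ± 0.06 and the mitophagy receptor BNIP3 at -1.65 ± 0.06. Oxidative phosphorylation genes instead had 23 rises and 3 falls of 39 (median 0.21, percentile 89.2), with NDUFB5 at 1.11 ± 0.07 and SDHB at 0.82 ± 0.06. Set directly against the SP1 siRNA library, 30 of these 39 genes were higher and 1 was lower with the SP3 siRNA by limma (32 and 1 adjusted over the list alone, median 0.34). Over all genes, that direct comparison called 7353 of 11728. The percentiles of the cholesterol, fatty acid and glycolysis medians were 0. ACLY, BNIP3 and NDUFB5 passed the threshold in the additive model, and ACAT2 (-0.99), DHCR7 (-0.67), FASN (-1.14), GAPDH (-0.81), PGAM1 (-0.93), SCD (-0.88) and SDHB (0.58) did not (adjusted p 0.0541 to 0.241).

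Of 21 NF-kB and cytokine genes 16 fell and 2 rose (median -0.53), with the adhesion molecule ICAM1 at -1.99 ± 0.09, CCL20 at -1.96 ± 0.11 and TNFAIP2 at -1.53 ± 0.09. Interferon genes had 12 falls and 4 rises of 22 (median -0.40), with OAS3 at -1.51 ± 0.09 and IRF7 at 1.17 ± 0.08. Textbook SP1 targets had 18 falls and 7 rises of 31 (median -0.35). They overlap other lists, with TK1 also among replication genes, CCNE1 among cyclins and FASN among fatty acid synthesis genes. EGFR, the epidermal growth factor receptor, fell from 18.8 and 17.4 to 4.41 FPKM (-1.82 ± 0.10). Epithelial genes had 10 falls and 5 rises of 20 (median -0.23), with ELF3 at -1.54 ± 0.06, CLDN4 at -1.48 ± 0.05 and KRT18 at -1.39 ± 0.05. WNT targets had 10 falls and 2 rises of 16 (median -0.21), with MYC at -0.99 ± 0.06 and DKK1 at 0.79 ± 0.07. Ribosomal protein genes had 21 falls and 5 rises of 54 (median -0.08). Antioxidant genes had 8 falls and 7 rises of 21 (median -0.05), with TXNRD1 at -1.25 ± 0.06 and GCLC at 1.05 ± 0.08. Autophagy and lysosome genes had 15 rises and 9 falls of 32 (median 0.03), with NEU1 at -1.25 ± 0.07. Immediate early genes had 11 rises and 6 falls of 23 (median 0.16), with EGR1 at 1.32 ± 0.10. Apoptosis regulators had 12 rises and 9 falls of 29 (median 0.02), with PMAIP1 at 1.19 ± 0.07. Targets of p53 had 8 rises and 4 falls of 26 (median 0.11), with GADD45A at 1.05 ± 0.08 and CDKN1A at -0.76 ± 0.06. For mesenchymal genes, with 12 rises and 6 falls of 27, the median was -0.08 and the mean 0.10, and PLAU lay at -1.58 ± 0.07. The ATF4 list had 8 rises and 8 falls of 30, a median of -0.007 and a mean of 0.04, with ASNS at 1.92 ± 0.08. In the SP and KLF family, 6 rose and 5 fell of 18, the median was -0.06 and the mean 0.14, and KLF5 rose by 1.44 ± 0.07. The falls of this family include SP3, the siRNA target, and SP1. Histone genes, the marker of RNA type, had 9 rises and 0 falls of 10 (median 1.24). Adjusted over the list alone, the counts of rises and falls were 2 and 17 for NF-kB, 2 and 14 for fatty acid synthesis, 5 and 17 for ribosomal proteins and 15 and 10 for autophagy, and were as over all genes for the others. Among the genes named here, CCL20 (-0.78), CLDN4 (-0.97), NEU1 (-0.57) and OAS3 (-0.96) missed the threshold in the additive model (adjusted p 0.0661 to 0.376). The medians lay at percentile 0 for NF-kB, 0.46 for interferon, 0.005 for textbook targets, 2.11 for epithelial, 7.64 for WNT, 1.34 for ribosomal protein, 19.4 for antioxidant, 36.5 for autophagy, 82 for immediate early, 48.2 for apoptosis, 72 for p53, 20.5 for mesenchymal, 25.7 for ATF4, 31.5 for SP and KLF and 100 for histone genes. The leukocyte markers fell in this library too, 5 of 6 with a median of -1.13, and what share of the lower NF-kB genes comes from other cells was not tested.

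With the SP3 siRNA limma called 7225 genes, 3466 higher and 3759 lower, of which 352 rose and 533 fell by at least 2-fold. Without a filter it called 2106. By size alone 233 genes were higher and 277 lower than each control. The additive model called 1805 genes, 785 higher and 1020 lower, and of 106 named genes 57 kept their side of the threshold and 49 lost it. At a mean of at least 5 FPKM the balance was the opposite, with 2686 higher and 2287 lower.

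**Figure D3:**
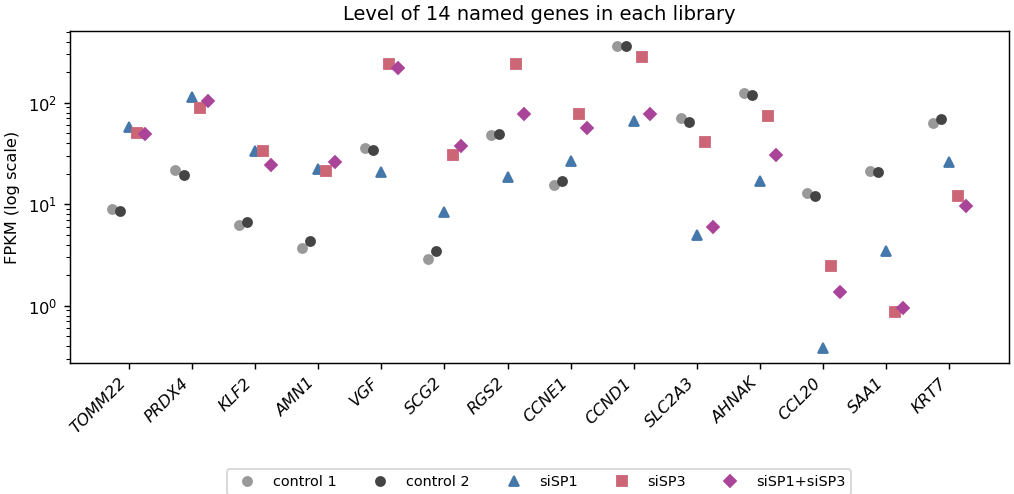
Points show FPKM on a log axis for 14 named genes in each of the 5 libraries. Cyclin D1 (CCND1) stands at 359 and 358 FPKM in the controls and at 65.8, 281 and 77.5 FPKM with the SP1 siRNA, the SP3 siRNA and both, and VGF at 35.9 and 34.3 FPKM against 20.9, 241 and 221 FPKM.

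The double knockdown was compared with the controls for genes that change when both factors are lowered. SCG2 (3.22 ± 0.10, limma adjusted p = 2.48e-12) and VGF (2.62 ± 0.06) rose, to 37.8 and 221 FPKM, as did ANKRD52 (2.48 ± 0.08), AMN1 (2.41 ± 0.09), TOMM22 (2.35 ± 0.07), PRDX4 (2.28 ± 0.07), the synuclein SNCG (2.28 ± 0.13) and SVBP (2.25 ± 0.08). No S100A9 read was found, which is at least 35.9-fold below the controls. Falls were also seen for SAA1 (-3.48 ± 0.11), SLC2A3 (-3.3 ± 0.08, to 5.92 FPKM), KRT7 (-2.66 ± 0.08), the cytochrome CYP2S1 (-2.53 ± 0.09), SPR, an enzyme of biopterin synthesis (-2.53 ± 0.10), SRPX (-2.51 ± 0.10) and CCL20 (-2.5 ± 0.11). CDKN1A, the CDK inhibitor p21, stood at 92.3 FPKM against 343 and 329 FPKM (-1.85 ± 0.06). It lay below the SP1 siRNA library by a log2 of -1.11 ± 0.07 and the SP3 siRNA library by -1.09 ± 0.07.

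Division genes fell less far in the double knockdown than in either single one. Over all tested genes 63% were called against the controls, 3736 higher and 3651 lower. Of 36 mitosis genes 27 fell and none rose (median -0.68), and of 38 replication genes 18 fell and 4 rose (median -0.22). Against the SP1 siRNA library 23 mitosis genes were higher and 0 lower, and 18 replication genes were higher and 2 lower. Against the SP3 siRNA library the counts were 26 and 1 for mitosis and 26 and 1 for replication. Over all tested genes 47.5% were called against the SP1 siRNA library and 33% against the SP3 siRNA library. All but 1 of 25 cholesterol synthesis genes fell (median -0.61), with EBP at -1.41 ± 0.07, while PMVK rose by 1.36 ± 0.11. Fatty acid synthesis had 10 falls and 3 rises of 16 (median -0.59), glycolysis and hypoxia 19 and 6 of 32 (median -0.26), interferon response 15 and 3 of 22 (median -0.61), NF-kB 15 and 1 of 21 (median -0.44), textbook SP1 targets 16 and 5 of 31 (median -0.50), epithelial genes 10 and 6 of 20 (median -0.28) and cyclins and CDK inhibitors 13 and 5 of 26 (median -0.24). KRT18 fell from 750 and 740 to 153 FPKM (-2.27 ± 0.05), EGFR stood at 3.34 FPKM, and the antioxidant enzymes HMOX1 and NQO1 fell by 1.70 ± 0.09 and 1.66 ± 0.08. Oxidative phosphorylation genes had 21 rises and 4 falls of 39 (median 0.18), histone genes 8 rises and 1 fall of 10 (median 0.75), and immediate early genes 11 rises and 5 falls of 23 (median 0.22), with FOS at 2.04 ± 0.12 and EGR1 at 1.76 ± 0.10. On immediate early genes the controls differed by 0.09. Leukocyte markers fell in the double knockdown too, 4 of 6 with 1 rise (median -0.85). What share of its lower NF-kB genes comes from other cells was not tested. Percentiles were 0 for mitosis, cholesterol, fatty acid, interferon and textbook target genes, 0.03 for glycolysis and for NF-kB, 0.5 for epithelial, 1.17 for cyclins, 1.19 for replication, 82.9 for oxidative phosphorylation, 90.6 for immediate early and 99.97 for histone genes.

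In the remaining lists, falls and rises numbered 11 and 6 of 27 for mesenchymal genes (median -0.17, with TIMP1 at 1.79 ± 0.06), 11 and 7 of 30 for ATF4 (median -0.18, mean -0.04), 8 and 4 of 16 for WNT targets (median -0.22), 14 and 8 of 38 for DNA repair (median -0.07), 9 and 5 of 21 for antioxidant genes (median -0.09), 11 and 9 of 29 for apoptosis regulators (median -0.06), 10 and 9 of 54 for ribosomal proteins (median -0.02), 8 and 11 of 32 for autophagy (median 0.08), 9 and 11 of 26 for p53 targets (median 0.04, mean -0.05) and 6 and 5 of 18 for the SP and KLF family (median -0.02, mean 0.01). Falls of the SP and KLF family include both siRNA targets, SP1 and SP3. Adjusted over the list alone, the counts of rises and falls were 4 and 10 for fatty acid synthesis, 8 and 8 for ribosomal proteins and 6 and 13 for cyclins, and as over all genes for the others. Limma called 7387 genes, 3736 higher and 3651 lower, of which 422 rose and 537 fell by at least 2-fold. The balance turned with median-ratio scaling, to 3533 higher and 3640 lower. By size 259 were higher and 293 lower than each control. Without a filter limma called 3157. Percentiles of the medians in these lists were 3.77 for mesenchymal, 0.82 for ATF4, 3.97 for WNT, 34.3 for repair, 8.92 for antioxidant, 24.8 for apoptosis, 4.28 for ribosomal protein, 56 for autophagy, 48.6 for p53 and 36.1 for SP and KLF genes.

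Markers of other cells were read in the same way. Of 12 leukocyte markers 6 reached 1 FPKM. LYZ, the lysozyme gene, stood at 11.1 and 12.2 FPKM in the controls, at 0.258 FPKM with the SP1 siRNA, at 3 reads with the SP3 siRNA (94-fold lower, 32.2- to 456-fold) and at 1 read in the double knockdown (259-fold lower, 46.5- to 10200-fold). TYROBP had 0 reads in all 3 knockdowns, at least 5.35-, 5.57- and 5.12-fold below its control level of 1.77 FPKM. CD14 had 2, 0 and 2 reads, and CD68 stood at 61.9 and 58.7 FPKM in the controls and at 56.2, 94.1 and 75.3 FPKM. The list median was -0.92, -1.13 and -0.85, or -0.93 in place of -1.13 with genes at 0 reads set to the floor, and above a mean of 5 FPKM it was 0.633 with the SP3 siRNA and 0.315 in the double knockdown. Only COL1A1 of 12 fibroblast markers was measured, at -0.50 ± 0.10, -0.09 ± 0.10 and -0.92 ± 0.10, the second short of the threshold. Of 8 embryonic kidney line markers 4 were measured, with medians of 0.49, -0.17 and 0.11 and a mean of 0.03 where the median was -0.17. For LYZ, TYROBP and CD14, as for S100A9 in each knockdown, the values do not settle whether the genes were regulated or other cells were present in the control cultures. PAX8 rose from 1.23 and 1.27 to 4.10, 2.79 and 7.04 FPKM. The percentiles were 0.01, 0 and 0.03 for leukocyte and 86.7, 39.2 and 66.9 for kidney line markers.

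Set against each single knockdown, the double knockdown stood nearer to the SP3 siRNA library. Compared with the SP1 siRNA, VGF (3.34 ± 0.07, limma adjusted p = 2e-13), SCG2 (2.05 ± 0.11) and RGS2 (1.99 ± 0.07) were higher and TOP1MT (-2.24 ± 0.10), the inositol synthase ISYNA1 (-2.01 ± 0.09) and the metalloproteinase MMP11 (-1.99 ± 0.13) were lower. Compared with the SP3 siRNA, IER5L (1.43 ± 0.08), FAM162A (1.31 ± 0.07) and SLX1B (2.85 ± 0.12), which has a near-identical copy and is uncertain, were higher, and SLC2A3 (-2.61 ± 0.09), CCND1 (-1.84 ± 0.06) and KIF1C (-1.83 ± 0.12) were lower. Limma called 5566 genes against the SP1 siRNA, 2467 higher and 3099 lower, and 3871 against the SP3 siRNA, 2104 higher and 1767 lower. These balances turned with median-ratio scaling, to 2613 higher and 2552 lower and to 1619 and 1744, and against the SP1 siRNA also at a mean of at least 5 FPKM (2172 and 1878). Without a filter limma called 0 genes in each, with 6063 and 4443 at an unadjusted p under 0.05 and 5763 and 4035 by limma-voom. By size, with no replicate on either side, 254 and 95 genes differed by at least 2-fold.

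Finally the single knockdowns were compared with each other. Among called genes, 1874 rose with both siRNAs, where independent lists would share 1266, and 1768 fell with both, where 1084 would be shared, while 710 higher and 619 lower genes of the SP1 siRNA went the opposite way with the SP3 siRNA. Set directly against each other, the single knockdowns differed in 7353 of 11728 genes by limma. Across genes their log2 differences from the controls correlated at a Pearson r of 0.43 and a Spearman rho of 0.39, with the same sign for 62.3%. Unchanged groups simulated against the same 2 controls gave a mean r of 0.329, 60.7% of equal sign and at most 3 shared rises and 2 shared falls. The covariance was 0.14 against a simulated mean of 0.00423, a difference of 0.136. The controls were too few to split with 2 on each side, so part of the excess in overlap may come from sharing them. The double knockdown correlated at 0.706 with the SP1 siRNA and at 0.809 with the SP3 siRNA. The interaction passed the limma threshold for 4630 genes, 2171 above and 2459 below the sum of the single differences. With median-ratio scaling it was 2081 and 2037, and without a filter limma called 0 (5376 at an unadjusted p under 0.05, 4733 by limma-voom). Of 3642 genes that changed in one direction in both single knockdowns, 2619 had an interaction against that direction and 9 with it. The interaction subtracts both single differences, and in the simulated unchanged groups it correlated with their sum at a mean r of -0.797. On this scale a level cannot fall below 0, so for 141 genes, 110 of them among the 2171, the interaction had to be above 0. For 258 genes past 2-fold in both, the median size was 1.36 with the SP1 siRNA, 1.34 with the SP3 siRNA and 1.46 in the double knockdown. These genes were selected by their size in those same single knockdown libraries, 1 each. Such selection alone can set the double knockdown below the sum of the single differences.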

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

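The tests of an RNA mixture, of shared or crossed controls and of the floor of the scale were chosen after the result they measure had been seen, and the removal of GC and length trends was added after the data were seen.

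The double knockdown difference departed from the sum of the single ones for 4630 of 11728 genes, by the limma interaction (adjusted p under 0.05). In 20 simulations of unchanged groups, with the same dispersion for all genes, at most 26 genes did so. A difference from the controls that all 3 knockdown libraries share would give such a departure too. The 4630 calls rest on 1 library per knockdown and the spread of 2 controls, and without a filter limma called 0 (5376 at an unadjusted p under 0.05, 4733 by limma-voom). The steepest departures above the sum of the single differences were those of RRM2, the ribonucleotide reductase subunit (2.97 ± 0.10 SE), CCL20 (2.73 ± 0.17) and the mitotic kinesin KIF18B (2.67 ± 0.18). A level cannot fall below 0, which alone holds the interaction of CCL20 at 1.48 or more and that of KIF18B at 0.64 or more, while that of RRM2 had room down to -2.38. RRM2 stood at 18.0 and 17.2 FPKM in the single knockdowns and at 40.0 FPKM in the double one, against 66.1 and 64.5 FPKM in the controls. Those farthest below the sum were ARL14EPL (-2.77 ± 0.12), KLF2 (-2.67 ± 0.12) and TOMM22 (-2.62 ± 0.11), which were high in all 3 knockdown libraries. Mitosis genes had 34 positive and 0 negative interactions of 36 (35 and 0 adjusted over the list alone, median 1.62, with 3 held above 0 by the floor), DNA replication genes 32 and 0 of 38 (33 and 0, median 0.90) and cholesterol synthesis genes 21 and 1 of 25 (median 0.78).

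Over 258 genes past 2-fold in both single knockdowns, the median ratio of the double knockdown to the sum of the single differences was 0.528. Crossed controls used one control for the single differences and the other for the double one. There, genes were selected anew by size alone, with no limma threshold, and the ratio was 0.517 over 263 genes and 0.503 over 267. Both selections used the same single knockdown libraries, 1 each, which by itself can overstate the single differences and lower the ratio. How much it did so was not tested. Over all genes the double difference was fitted by 0.429 times the SP1 siRNA difference plus 0.646 times the SP3 siRNA difference (R squared 0.813). A double library made by mixing RNA of the single ones is argued against: the mixing share that gives its SP1 level (97.8% from the SP1 siRNA library) would leave SP3 at 108% of control, and it was measured at 50.7% (46.9 to 54.8%). A GC trend and the floor of the scale as whole causes are also argued against, since the ratio was 0.526 after removal of the trend and 0.563 in the 91 genes that were higher, which no floor limits. What stays open, untested here, is that each siRNA may have been used at a lower amount in the double knockdown. Changes may also level off once either factor is low, or SP1 and SP3 may act on the same sites. A response to siRNA delivery, or handling, that sets all knockdown libraries apart from the controls would lower the ratio as well and was not tested.

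The single knockdowns shared part of their changes, with a covariance of 0.14 between their profiles. The spread between the shared control libraries as the whole cause is argued against, because the highest simulated covariance was 0.00458. The correlation with control 1 used for one profile and control 2 for the other was 0.42 or 0.401, close to 0.43. An offset common to both controls would escape these checks. GC content and transcript length as whole causes are argued against as well: r was 0.43 with the GC trend removed and 0.431 with the length trend removed, and the differences correlated with GC at 0.0245 for the SP1 siRNA and -0.0419 for the SP3 siRNA. A response to siRNA delivery that the control siRNA does not raise, or the handling of the knockdown cultures apart from the controls, may still account for it and cannot be tested with 1 library per knockdown. Under the hypothesis that SP1 and SP3 act on the same genes the same sharing would be seen.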

How the results depend on the processing

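Median-ratio scaling, limma-voom on recovered reads, and the removal of GC and length trends were chosen after the data were seen.

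No paired analysis was possible because each knockdown group has 1 library and shares fewer than 2 replicate numbers with the controls. Upper-quartile scaling, library-total scaling and count-model tests of the deposited values were not run, since the values were FPKM. With 1 control left out no residual degree of freedom remains, so these are values with no test. Of 632 differences of named genes 631 kept their direction. The largest rises and falls were named only where each control gave the same direction, so for them this outcome was fixed by the naming rule. List members were named by smallest p, which favours genes on which the 2 controls lie close beside the difference. For them too the outcome says little. PAX2 with the SP3 siRNA, short of the threshold with both controls (-0.12, limma adjusted p = 0.506), lay at 0.01 without control 1. The counts by size ranged from 678 to 711 (SP1 siRNA), 583 to 594 (SP3 siRNA), 628 to 630 (both) and 450 to 463 (interaction). Over all alternatives, 2573 of 2756 values of named genes kept their direction and, where tested, their side of the threshold. The 632 values with 1 control left out are among the 2756 and were judged by direction alone. Another 179 lost the threshold (116 in the additive model, 62 without a filter, 1 with a pseudocount of 0.1), and besides PAX2 there were 3 that reversed. HOXA11 with the SP1 siRNA, short of the threshold in each, went from 0.025 to -0.01 with median-ratio scaling (adjusted p = 0.941, and 0.662 to 0.909 in its other alternatives). In the additive model with the SP1 siRNA, FASN lay at 0.106 (adjusted p = 0.809) and SCD at 0.06 (0.881); their other 6 alternatives gave -0.51 to -0.45 with adjusted p of 1.77e-10 to 0.0444, and -0.49 to -0.43 with 1.84e-10 to 0.0407. The cause was not tested.

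Counts of called genes moved by over 1.5 times in these cases. Without a filter limma called 4180, 2106 and 3157 genes for the SP1 siRNA, the SP3 siRNA and both, and 0, 0 and 0 for the double knockdown against the SP1 siRNA, against the SP3 siRNA and for the interaction. At an unadjusted p under 0.05 these last were 6063, 4443 and 5376, and limma-voom called 5763, 4035 and 4733. Without a filter 771 of 17125 genes were at 0 FPKM in both controls and so had no spread, where 0 of 11728 genes had equal controls with the filter, and the prior degrees of freedom dropped from 13.98 to 1.03. A mean of at least 5 FPKM gave 5109 for the SP1 siRNA, with fewer genes tested. The additive model gave 900 and 1805 for the SP1 and SP3 siRNAs, where departure from the sum counts as spread. A log2 difference of at least 1 gave, by its own construction, 1014, 885, 959, 394, 132 and 687 in the order of the 6 comparisons, and a 1.5-fold limit on size gave 1833, 1669, 1730, 1226, 679 and 1366. Limma-voom counts moved by less than 1.5 times. It called 8632, 7840, 7968, 5763, 4035 and 4733 genes, of which 7307, 6875, 6949, 5042, 3374 and 4058 were the same genes in the same direction.

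The balance of higher and lower genes turned in several cases, and that of the SP1 siRNA became nearly even with median-ratio scaling (3725 and 3649). Against the SP1 siRNA the double knockdown had 2172 higher and 1878 lower at a mean of at least 5 FPKM and 2613 and 2552 with median-ratio scaling, and against the SP3 siRNA 1619 and 1744 with median-ratio scaling. Against the controls the SP3 siRNA had 2686 and 2287 at a mean of at least 5 FPKM, the double knockdown 3533 and 3640 with median-ratio scaling and the SP1 siRNA 432 and 468 in the additive model. The interaction had 2081 above and 2037 below the sum with median-ratio scaling.

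Shifts of gene list medians were set against the median control difference of the list divided by the square root of 2. Of these medians 169 moved by no more than that and 138 by more. With 1 control left out the shift comes from that same control difference, so for those values the comparison says little. Another 2 reversed: leukocyte markers at a mean of at least 5 FPKM lay at 0.633 (SP3 siRNA) and 0.315 (both), where only CD68 is left. The similarity of the single knockdowns stayed within 0.401 and 0.431. Median-ratio factors lay between -0.02 and 0.05 on the log2 scale. With limma-voom the median over all genes was 0.11 higher for the SP1 siRNA than in the controls. Depth limits genes with few reads: S100A9, at 1 read with the SP3 siRNA, has an interval of 21- to 4630-fold. With 1 library per knockdown, a difference in handling of 1 culture cannot be separated from the knockdown.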

Other observations

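The direct difference between the SP3 and SP1 siRNA libraries and the genes named singly here were chosen after their values were seen. The rule for the scan of short words in 3' UTRs was written before the scan and was split by library after it. The rule for their share among lower genes was written after the scan and before the shares were seen, and was split by library afterwards.

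With a mean of at least 5 FPKM, 8 genes went past 2-fold in opposite directions in the single knockdowns. AKAP12, a scaffold for protein kinase A, rose from 240 and 223 FPKM to 530 FPKM with the SP1 siRNA and fell to 79.2 FPKM with the SP3 siRNA (siSP3 minus siSP1 -2.73, limma adjusted p = 4.41e-13). The hypoxia-induced carbonic anhydrase CA9 went from 4.55 and 3.96 FPKM to 13.6 and 1.21 FPKM, and RBMX, which has near-identical copies and is uncertain, from 22.7 and 21.3 to 48.8 and 10.2 FPKM. The other 5 went down with the SP1 siRNA and up with the SP3 siRNA. RGS2 went from 47.7 and 49.2 to 18.7 and 238 FPKM (3.60, adjusted p = 5.78e-14), the actin crosslinker FLNC from 31.6 and 34.8 to 15.8 and 80.5 FPKM, FAM131A from 8.32 and 8.51 to 3.64 and 19.1 FPKM, and the histone genes HIST1H2BC and HIST2H2BE, from a family with shared sequence, from 20.5 and 21.5 to 9.07 and 76.1 FPKM and from 31.3 and 47.1 to 17.1 and 104 FPKM. Of 10 histone genes 9 were higher with the SP3 siRNA than with the SP1 siRNA and 0 lower (9 and 0 adjusted over the list alone, median 1.34). Over all genes, limma called this direct difference for 7353 of 11728. This list was set as a marker of RNA type, so a difference in RNA selection between libraries is not excluded for it. The cell cycle transcription factor E2F1 stood at 4.77 and 5.33 FPKM in the controls, at 1.81 FPKM with the SP1 siRNA and at 6.66 FPKM with the SP3 siRNA (1.45, adjusted p = 1.75e-07).

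The 12 keratin genes with a mean of at least 1 FPKM, a group chosen after their values were seen and not tested as a list, went different ways. KRT18 stood at 745 ± 7.45 FPKM in the controls (SD, n = 2) and at 408, 284 and 153 FPKM with the SP1 siRNA, the SP3 siRNA and both, while its filament partner KRT8 stood at 1770 ± 35.7 FPKM and at 1740, 2360 and 2250 FPKM. KRT7, KRT80 and KRT81 fell in all 3, with log2 differences of -2.66, -2.01 and -1.98 in the double knockdown, as did KRT86 (-0.9). In the double knockdown KRT23 (1.09), KRT32 (0.85), KRT10 (0.56) and KRT15 (0.54) were higher, KRT13 lay at 0.15, short of the threshold, and the abundant KRT19 lay at -0.1, 0.09 and 0.23 in the 3 knockdowns. These directions held with median-ratio scaling. KRT81 has a close relative, KRT86, that can share its reads. Several of the most abundant transcripts moved as well. GAPDH, often used as a reference gene, went from 9740 ± 25.7 FPKM to 5810, 4120 and 4910 FPKM, the actin ACTG1 from 8920 ± 598 to 3700, 6110 and 6040 FPKM, and the actin-binding TMSB10 from 4790 ± 28.4 to 5230, 12300 and 9890 FPKM. Inflammation-related S100A8 (4.30 and 4.33 FPKM in the controls) stood at 0.718, 0.0862 and 0 FPKM, for which a loss of other cells present in the control cultures was not ruled out, SAA2 (2.57 and 2.86 FPKM) at 0.335, 0.188 and 0.175 FPKM, and the telomerase gene TERT (2.51 and 3.07 FPKM) at 1.13, 0.327 and 0.475 FPKM. The synaptic vesicle gene SYP stood at 0.917 and 0.827 FPKM in the controls and at 0.857, 5.17 and 7.31 FPKM.

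Off-target action of the siRNAs was weighed as an explanation of part of the lower genes. An siRNA can lower transcripts whose 3' UTR matches its seed, a run of bases near its 5' end. The siRNA sequences are not given in the sources used here, so all 7-base words were scanned. With the SP3 siRNA the most negative word was TAGCAGT, with a z of -8.02 and a log2 shift of -0.147 over 1104 genes. It reached -6.59 in the double knockdown and -0.96 with the SP1 siRNA, as a seed effect of the SP3 siRNA would, and the lowest word between the controls had -3.37. The preset limit for the most negative word was -8, which TAGCAGT passed only narrowly. With the SP1 siRNA it was CAGGTGT (z -8.50, shift -0.133, 1959 genes), with 1.52 for the SP3 siRNA and -3.63 in the double knockdown, which missed the preset limit of -4. The overlapping AGGTGTT, AGGTGTA and GGTGTTT reached -4.12, -4.66 and -4.97 there, while the overlapping AGGTGTC, at -2.73, missed it too. CAGGTGT lies far below the lowest word between the controls as well. Whether it comes from the seed of the SP1 siRNA stays open, because the limit in the double knockdown was missed.

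Both shared 6-base cores, AGGTGT and AGCAGT, occur in the transcript each siRNA targets. A long transcript holds many 6-base words, so this presence weighs little. They were present in 43.5% and 43.3% of genes lower by at least 2-fold, in 35.6% and 39% of all searched genes, and in 27% and 28.1% of genes higher by at least 2-fold. If AGCAGT is the core of the SP3 siRNA seed, direct seed matches as the whole cause of its lower genes are argued against, because 56.7% of these genes lack it. For the SP1 siRNA 56.5% lack AGGTGT, past the limit of 50% set for the rule, but this decides nothing while it is open whether AGGTGT belongs to its seed. Effects further downstream of seed-matched genes were not tested. A share of the moderate falls may still come from seed matches, and a second siRNA of other sequence against each target would test this.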
